A study of Mus musculus with 14 samples.

How the data were processed

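Bulk libraries were made from cells sorted as CD4 positive from marrow and spleen. RNA was extracted with TRIzol, polyadenylated RNA was selected and libraries were built with NEBNext Ultra reagents per the labels. The deposited bulk tables hold whole-number read counts per gene symbol, with separate entries for reads outside genes and for ambiguous reads, which the authors counted on mm10 per the submitters' processing notes. The aligner, the counter, the gene annotation and the use of strand are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The deposited single-cell matrices hold whole-number UMI counts per gene and barcode for the barcodes called as cells, made by the authors with Cell Ranger 3.0.2 per the submitters' processing notes from 10x 3' v2 libraries. Groups and library numbers were taken from the sample titles. Gene positions come from the GENCODE annotation of mm10.

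Comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. Bulk counts were analysed in R 4.3.3 with edgeR 4.0.16. The entries for reads outside genes and ambiguous reads were left out, genes were filtered with filterByExpr, libraries were scaled by TMM, and a quasi-likelihood F test with robust dispersion was applied, two-sided, with Benjamini-Hochberg adjustment over tested genes and a threshold of 0.05. Knockout and control were compared within each tissue on 6 libraries. The interaction of genotype and tissue, and marrow against spleen within each genotype, were tested in a fit of all 12 libraries in 4 groups. CPM values are given as mean ± SD, and log2 fold changes with the standard error of the fit. The 12 pairs of libraries within a group were compared by a chi-square test of their counts, which gave 8.75 to 15.1 per degree of freedom, so in none of these pairs had 1 library been deposited under 2 names. Pairs across groups were not compared this way.

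The 43 gene lists covered immune pathways, T cell states, glycan enzymes, metabolism and markers of other cell types. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. Members past the threshold were counted over all genes and after adjustment over the list alone. A gene was named when its adjusted p was under 0.05, its mean CPM at least 5 and its groups did not overlap, taking the 10 largest log2 fold changes each way without predicted gene models and receptor segments. Where fewer than 10 genes passed, the 10 with the smallest p were given as values, and members of fixed lists past the threshold could also be named.

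Single cells were analysed in Python 3.11.15 with scanpy 1.11.5. Barcodes with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were kept, 8161 in the control and 7393 in the knockout. The automatic Scrublet threshold called 0 doublets in each library, so the barcodes with the highest scores were removed instead, 0.8% per 1000 barcodes of the library, which took 609 (7.46%) and 526 (7.11%). This replacement was made after the automatic result was seen. The 7552 and 6867 kept cells were scaled to 10000 UMIs and clustered on 2000 variable genes, 30 principal components and 15 neighbours with leidenalg 0.10.2 at resolution 1, without integration of the libraries. Immunoglobulin, T cell receptor, interferon-responsive, interferon, sex-linked, mitochondrial and ribosomal protein genes were kept out of clustering. The 31 clusters were named from 20 marker sets. A set was met with a mean log2 fold of at least 0.8 and at least 3 markers above a log2 fold of 1. A cluster that met several sets took the one with the highest mean. It was left unnamed if another met set had a mean of at least 1 and was not compatible. The B cell, B cell precursor and plasma cell sets were compatible with each other. Clusters that met no set, or had more leading genes of another set, were also left unnamed. So were low-UMI clusters without a leading gene of their set.

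Within each class of at least 100 cells in each library, UMIs were summed over cells and compared as CPM. Ratios carry an exact conditional binomial 95% interval and shares of cells an exact Clopper-Pearson interval, both for counting error only. A gene was named with at least 50 UMIs in 1 library and a ratio of at least 2 either way, taking the 10 largest and 10 smallest. List medians were taken over members with at least 20 UMIs on log2 ratios of CPM plus 1. They were placed among 10000 random lists matched on size and mean expression, with counting intervals from 1000 resamples. For shares of cells with an immunoglobulin UMI, each cell was thinned to 1500 UMIs and cells below that depth were left out, 45 control and 34 knockout pDC-like cells.

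The tests were checked on simulated data. With added changes of 0.5, 1 and 2 on the log2 scale in marrow counts, 16 of 67, 41 of 67 and 51 of 66 genes were recovered, with 9 false calls, so changes near 0.5 are mostly missed with 3 libraries per group. In sums of pDC-like cells 200 of 200 added changes were recovered.

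Alternatives were other normalizations (RLE, upper quartile), no or a stricter expression filter, DESeq2 1.42.0, limma-voom, an added minimum log2 fold change of 1, 1 fit of all 12 libraries, leaving out genes of other cell types, a replicate block, and leaving out each library in turn. For single cells they were other resolutions (0.5 and 2), a loose cell filter (200 genes, 20% mitochondrial), no doublet removal, clustering with immunoglobulin and interferon genes, other totals and equal weights per cell. Chosen after seeing the data were the Xist level as a covariate, removal by a doublet score above 0.25, leaving out barcodes of the other library and leaving out the interferon-led cluster. Figures were drawn with matplotlib 3.10.9.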

Results

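Messenger RNA was sequenced from CD4 sorted cells of bone marrow and spleen and from single marrow cells of mice carrying floxed St3gal1 alleles. St3gal1 encodes a sialyltransferase that adds sialic acid to O-linked glycans, and Pf4 encodes platelet factor 4, whose promoter drives cre in megakaryocytes. Mice with floxed alleles and Pf4/cre are called knockout here, and mice with the floxed alleles alone are called control. The bulk data comprised 12 libraries, 3 per genotype in each tissue. They held 6418293 to 8791627 gene counts in marrow and 5112239 to 8335371 in spleen, and 13247 to 16377 genes were detected per library. Reads outside annotated genes made up 33.5% of control spleen library 9 and 22.4% to 27.1% of the other 11 libraries. The single-cell data comprised 1 control and 1 knockout library of marrow cells sorted as positive for B220 and CD11c and negative for Ter119, CD11b, CD8 and Gr1. These libraries held 9331 and 8898 barcodes, with a median of 4125 and 4186 UMIs per barcode. Replicates are separate libraries per the labels, so the p-values of the bulk comparisons measure only the spread between these libraries. An exact permutation test of 3 against 3 libraries cannot go below 0.10, so the bulk comparisons rest on models fitted across all genes.

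St3gal1 was read in every CD4 library and did not pass the test in either tissue. In marrow, its level was 126, 142 and 144 CPM in control libraries 1, 4 and 9 and 127, 116 and 143 CPM in knockout libraries 5, 6 and 10. In spleen, it was 161, 153 and 162 CPM in control libraries 3, 4 and 9 and 150.2, 142 and 153 CPM in knockout libraries 6, 8 and 10. The log2 fold change of St3gal1, knockout over control, was −0.08 ± 0.11 (SE, n = 3 per group) in marrow and −0.09 ± 0.11 in spleen, with edgeR adjusted p = 0.869 and 1.00. St3gal1 lies on chromosome 15 of mm10, from 67102875 to 67176830. Pf4, a megakaryocyte gene, stood at 3.36 ± 2.16 CPM in control and 2.10 ± 2.48 CPM in knockout marrow (SD, n = 3), and at 11.1 ± 7.96 and 10.7 ± 7.73 CPM in spleen. Because Pf4/cre acts in megakaryocytes, the level of St3gal1 in CD4 cells or in sorted dendritic cells does not test whether the allele was deleted. In single marrow cells, St3gal1 had 23.8 CPM in the control and 24.1 CPM in the knockout library over all kept cells.

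The CD4 libraries carried transcripts of B cells in all 4 groups. Cd79a, a chain of the B cell receptor complex, ranged from 530.0 to 675 CPM over the 12 libraries, while Cd4 ranged from 173 to 327 CPM and Cd3e, a chain of the T cell receptor complex, from 179 to 295 CPM. Siglech, a marker of plasmacytoid dendritic cells, averaged 240 CPM in control and 319.8 CPM in knockout marrow but 7.34 and 8.40 CPM in spleen. Xist, which is transcribed in female cells, ranged from 131 to 604 CPM, and the Y-linked Ddx3y from 86.2 to 185 CPM, so each of the 12 libraries held both a transcript of female cells and a Y-linked one.

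The first bulk comparison asked which transcripts of marrow CD4 cells differed between knockout and control mice. Several T cell genes fell in the knockout libraries. Cd247, the zeta chain of the T cell receptor complex, fell by 0.91 on the log2 scale (SE 0.11, adjusted p = 0.000184), from 165 ± 14.6 to 88.3 ± 7.31 CPM (SD, n = 3). Cd3e fell by 0.56, Cd3g by 0.58, Cd5 by 0.60 and Lck, the kinase that starts receptor signalling, by 0.59, with adjusted p from 0.000668 to 0.00198. Gimap7, a GTPase of lymphocytes, fell by 0.86 (adjusted p = 0.000419) and S100a10, a member of the S100 family, by 0.58 (adjusted p = 0.00198). In the same libraries, B cell and antigen presentation genes were higher: the invariant chain Cd74 rose by 0.26 (adjusted p = 0.00658), H2-Ab1 by 0.29 (adjusted p = 0.0183) and Cd22, a sialic acid-binding receptor of B cells, by 0.34 (adjusted p = 0.0162).

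**Figure D1:**
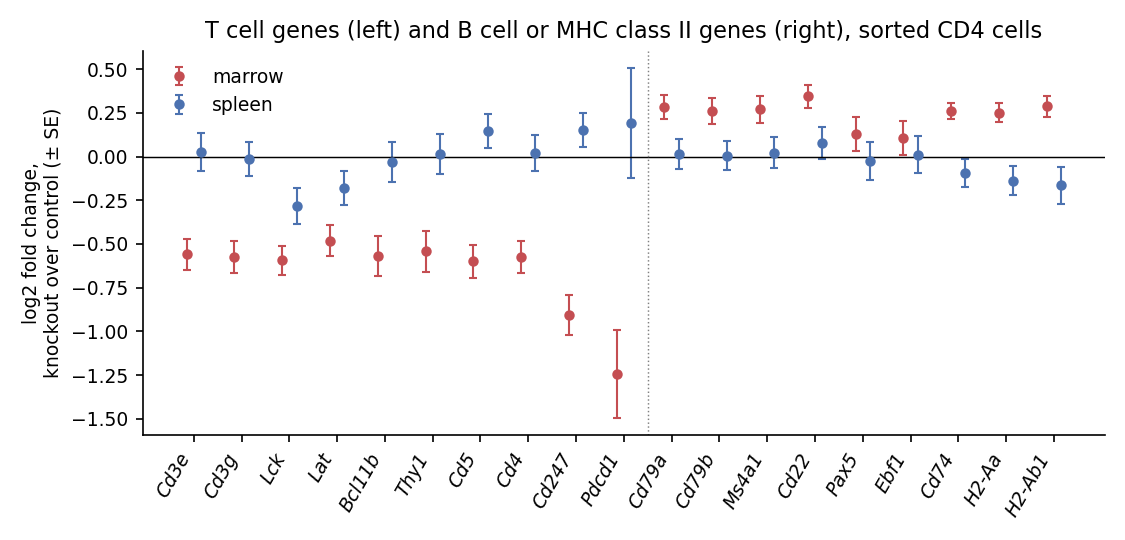
Log2 fold change, knockout over control, with its standard error (edgeR, n = 3 per group) for T cell genes at left and B cell and MHC class II genes at right, in marrow and in spleen. In marrow Cd3e stood at −0.56 and Cd74 at 0.26.

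In all, 85 of 12044 tested marrow genes passed the edgeR threshold, 27 higher and 58 lower in the knockout, with a median size of 0.53 on the log2 scale, and 1278 genes had an unadjusted p under 0.05 (602 by chance). All 3 knockout libraries lay on one side of all 3 controls for each of the 85 genes, against 15.7% of all tested genes and a chance share of 10%. Among genes with a mean CPM of at least 5, the steepest falls were those of Igfbp4, an insulin-like growth factor binding protein expressed by naive T cells (−1.61, SE 0.29, adjusted p = 0.0114), Ccdc92 (−1.39, adjusted p = 0.0400), the co-chaperone Dnaja4 (−1.39, adjusted p = 0.0249) and the inhibitory receptor Pdcd1 (−1.24, SE 0.25, adjusted p = 0.0173). Pdcd1 fell from 33.1 ± 6.71 to 14.0 ± 2.63 CPM. Tmem176b, Arhgap31, Entpd1, an ectonucleotidase, and Vps26b fell by 0.80 to 0.94. The greatest rise among them was that of the ephrin receptor Epha2 (1.08, SE 0.24, adjusted p = 0.0401), from 24.2 to 51.0 CPM. The cytosolic DNA sensor Aim2, the phosphatase Dusp4, the cholesterol exporter Abca1, the glycosyltransferase B3gnt5, Ppp5c, the insulin receptor substrate Irs2, H2-DMb2, the kinase Lrrk2 and the fatty acid desaturase Scd1 rose by 0.41 to 0.56. Cd247 lies on chromosome 1 of mm10 from 165788681 to 165877277, Pdcd1 on chromosome 1 from 94038305 to 94052553, and Igfbp4 on chromosome 11 from 99041244 to 99054392.

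These marrow calls depended on single libraries. Of 48 named genes past the threshold, Cd247, Gimap7, S100a10, Cd3e, Cd3g, Lck and Cd5 stayed past it whichever of the 6 libraries was left out. The other 41 missed it without control library 9, and 31, 34, 33, 18 and 11 missed it without control 4, knockout 5, knockout 6, knockout 10 and control 1, though all 48 kept their direction. Across all alternative fits the highest adjusted p was 0.00923 for Cd247, 0.233 for Pdcd1, 0.197 for Igfbp4, 0.482 for Epha2 and 0.295 for H2-Ab1. The number of called genes was 11 without control 9, 23 without knockout 5 or 6, 33 without control 4 and 133 without control 1, and it was 15 with the Xist level as a covariate, an alternative chosen after seeing the data. With that covariate S100a10 missed the threshold (adjusted p = 0.0871), and Cd247, Gimap7, Cd3e, Cd3g, Lck and Cd5 stayed past it (highest adjusted p = 0.045).

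Of 40 gene lists tested in marrow, camera called 17 with its preset correlation of 0.01, of which 0 held with an estimated correlation. All 14 tested members of the B cell list were higher in the knockout (median log2 fold change 0.27), 4 of them past the threshold over all genes (Cd74, Cd22, Fcer2a and Fcmr) and 12 when adjusted over the list alone. The camera test gave adjusted p = 1.64e-07, and adjusted p = 0.3 with an estimated correlation. Of 14 genes of MHC class II presentation, which display peptides to CD4 T cells, 6 rose over all genes (Cd74, H2-Ab1, H2-Eb1, H2-Aa, H2-DMb2 and H2-Ob) and 10 when adjusted over the list alone. Their median was 0.27, with adjusted p = 1.32e-05, and adjusted p = 0.296 with an estimated correlation. The plasmacytoid dendritic cell list had a median of 0.37, with 14 of 15 members higher, none past the threshold over all genes and Ly6d and Spib past it when adjusted over the list alone (camera adjusted p = 0.00796, and adjusted p = 0.594 with an estimated correlation). The plasmacytoid dendritic cell list was not called without control 9, knockout 5 or knockout 6.

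Genes that mark memory and effector T cells were lower in knockout marrow, with a median of −0.36 over 31 genes. S100a10, Ahnak, the integrins Itgb1 and Itgb7 and the chemokine receptor Cxcr3 fell over all genes by 0.35 to 0.63, and 11 fell when adjusted over the list alone. The camera test gave adjusted p = 2.77e-06, and adjusted p = 0.160 with an estimated correlation, while fry, which tests whether the members move on balance one way, gave adjusted p = 0.0448. Of the marrow lists that camera called, this was the single one that fry called too. The fixed set of 9 T cell markers fell further, with a median of −0.57, so the fall of this list does not by itself show a change of T cell state. Among these markers Lat, Bcl11b and Thy1 fell by 0.48 to 0.57. Cd3d at −0.58 (adjusted p = 0.0724) and Cd28 at −0.39 (adjusted p = 0.311) did not pass. Cd4 had a log2 fold change of −0.58. Of 33 genes of the interferon gamma response, the MHC class I genes H2-D1, H2-K1 and B2m fell by 0.23 to 0.29, 6 members fell and Ciita rose when adjusted over the list alone, and the median was −0.17 (camera adjusted p = 0.00173, and adjusted p = 0.338 with an estimated correlation). The type I interferon response list of 67 genes had a median of −0.11. Its camera test gave adjusted p = 0.0430, and adjusted p = 0.336 with an estimated correlation. Ifi47, an interferon-induced GTPase, fell by 0.55, Mnda fell from 4.44 to 0.0767 CPM, and adjusted over the list alone 1 member rose and 3 fell. Genes of the H2, Gimap and Ifi families have near-identical relatives, so the assignment of their reads is uncertain. Without control 1, control 4 or knockout 5 the type I list was not called, and without control 1 the interferon gamma list was not called.

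Lists of activation, division and lipid synthesis were called too. Of 33 genes of the immediate early and T cell receptor signalling list, which respond to receptor signalling, Dusp4 rose over all genes and 5 when adjusted over the list alone, among them Cd69 and Nr4a1 (median 0.26, camera adjusted p = 2.77e-06, and adjusted p = 0.375 with an estimated correlation). Of 40 cell cycle genes, none passed over all genes and Rrm2, a ribonucleotide reductase subunit, fell when adjusted over the list alone (median −0.21, camera adjusted p = 2.77e-06, and adjusted p = 0.296 with an estimated correlation). Of 20 genes of cholesterol synthesis, none passed over all genes, and Srebf2 and Cyp51 rose when adjusted over the list alone (median 0.18, camera adjusted p = 0.00755, and adjusted p = 0.296 with an estimated correlation). This list was not called without control 1. Among regulatory T cell genes, Izumo1r (−0.68, adjusted p = 0.00704) and Entpd1 fell and Swap70 rose, while Foxp3, the factor that defines these cells, stood at −0.36 (adjusted p = 0.109) and the list was not called (camera adjusted p = 0.186).

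The second comparison put the same question to CD4 cells of the spleen. Neutrophil granule genes rose in the knockout libraries. Elane, or neutrophil elastase, rose by 2.77 on the log2 scale (SE 0.32, adjusted p = 0.000145), from 4.72 ± 0.459 to 32.4 ± 9.56 CPM (SD, n = 3). The antimicrobial peptide gene Camp rose by 1.92 (adjusted p = 0.000621) and the siderophore-binding Lcn2 by 1.89 (adjusted p = 0.00410). Ikzf2, which encodes Helios, a transcription factor of regulatory T cells, rose by 0.85 (SE 0.16, adjusted p = 0.0413), from 63.1 ± 7.48 to 114 ± 25.9 CPM. In each of these 4 genes all 3 knockout libraries lay above all 3 controls.

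These 4 were the called genes among 12135 tested, with 0 lower. An unadjusted p under 0.05 was reached by 560 genes (607 by chance), and 10.3% of all genes had groups that did not overlap (10% by chance). DESeq2 called 19, 12 higher and 7 lower, and limma-voom 5, all higher. Genes with the next smallest p did not pass: S1pr5, a receptor for egress, stood at 1.88 CPM in knockout and 14.8 CPM in control spleen (adjusted p = 0.0574), the interferon-induced GTPase Igtp at −0.68 (adjusted p = 0.110), Ltf, or lactoferrin, at 2.10 (adjusted p = 0.147), Hap1 at −2.36 (adjusted p = 0.154) and Mpo at 0.97 (adjusted p = 0.175). Krt80 was listed at 0 in all 3 knockout libraries and stood at 5.39 ± 5.62 CPM in controls (adjusted p = 0.158). Elane lies on chromosome 10 of mm10 from 79886247 to 79888215.

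Of 39 lists tested in spleen, camera called 5, of which 0 held with an estimated correlation and 0 were called by fry. The neutrophil list had a median of 1.83 over 14 genes, 3 of them past the threshold over all genes and 9 when adjusted over the list alone (camera adjusted p = 3.37e-11, and adjusted p = 0.667 with an estimated correlation). Of 23 regulatory T cell genes, Ikzf2 rose over all genes and 6 when adjusted over the list alone, with Foxp3 at 0.56, Ctla4 at 1.01 and Nrp1 at 0.65 among them (median 0.17, camera adjusted p = 0.00297, and adjusted p = 0.827 with an estimated correlation). Conventional dendritic cell genes had a median of −0.37 with 0 of 13 positive (camera adjusted p = 0.000622, and adjusted p = 0.827 with an estimated correlation). Immediate early genes had a median of 0.20 (camera adjusted p = 0.000766) and basophil genes one of 1.12 (camera adjusted p = 0.0264), each with adjusted p = 0.827 with an estimated correlation. Lcn2 was not called without control 9 or knockout 10, Ikzf2 without control 3, control 9, knockout 6 or knockout 10, the regulatory T cell list without knockout 8, the immediate early list without control 3 or knockout 10, and the basophil list without control 3, control 4 or knockout 10. Across all alternative fits the highest adjusted p was 0.057 for Elane, 0.764 for Camp, 0.426 for Lcn2 and 0.802 for Ikzf2, the first 3 in a fit of all 12 libraries together. The count of genes was 8 without control 3, 11 without control 4, 2 without control 9, 42 (15 higher and 27 lower) without knockout 8 and 2 without knockout 10. When genes of other cell types were left out, edgeR called 0 genes (560 at an unadjusted p under 0.05). That fit removes the neutrophil list, and with it Elane, Camp and Lcn2, before testing, so of the called genes it tests Ikzf2 alone.

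Whether the genotype effect differed between marrow and spleen was tested as an interaction. Several T cell genes differed in their genotype effect between the tissues. As a set, the 9 T cell markers fell in knockout marrow (median −0.57). The interaction test does not separate a lower share of T cell RNA there from a change within T cells. The interaction, marrow minus spleen, was −1.06 for Cd247 (SE 0.145, adjusted p = 0.000141), which changed by −0.91 in marrow and 0.15 in spleen. It was −0.75 for Cd5 (SE 0.129, adjusted p = 0.00513), an inhibitory T cell coreceptor at −0.60 and 0.14 in the tissues, and −0.93 for Foxp3 (SE 0.158, adjusted p = 0.00513), at −0.36 in marrow and 0.56 in spleen. S100a10 had an interaction of −0.72 (adjusted p = 0.0143) and the adhesion receptor Cd2 one of −0.67 (adjusted p = 0.0388). The neutrophil genes Elane (−4.05, adjusted p = 0.0143) and Itgb2l (adjusted p = 0.0313) were also called. Itgb2l was listed at 0 in all 3 control spleen libraries and stood at 4.68 ± 3.51 CPM in knockout spleen, so its fitted value is no bound.

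The edgeR interaction test called 7 of 12875 genes, 0 higher and 7 lower, with 902 at an unadjusted p under 0.05 (644 by chance), 26 called by DESeq2 and 2 by limma-voom. DESeq2 gave no adjusted p for 8237 of the genes, so it adjusted over fewer. No gene was called in both tissues, and 55 of the 85 marrow genes had the same sign in spleen. Across 11621 genes, the fold changes in marrow and spleen had Pearson r = 0.0824, where genes are not independent replicates. Of 40 lists, camera called 14 for the interaction, of which 0 held with an estimated correlation. Among them were MHC class II presentation (median 0.36, 0 members over all genes and 7 adjusted over the list alone, adjusted p = 2.35e-05, and adjusted p = 0.219 with an estimated correlation) and regulatory T cell genes (median −0.60, Foxp3 over all genes, and Nrp1 and Ikzf2 also adjusted over the list alone, adjusted p = 0.00210, and adjusted p = 0.379 with an estimated correlation). Fry called the thymocyte list (median −0.91, camera adjusted p = 0.00996, adjusted p = 0.151 with an estimated correlation, fry adjusted p = 0.0354). Across all alternative fits the highest adjusted p was 0.00166 for Cd247, 0.14 for Foxp3, 0.0545 for Cd5, 0.0982 for S100a10, 0.219 for Elane, 0.66 for Itgb2l and 0.288 for Cd2. Cd247, Foxp3 and Cd5 were called whichever of the 12 libraries was left out, and S100a10 missed the threshold without marrow knockout 5 or spleen control 3 or 9. Elane missed it without marrow knockout 10, spleen controls 3, 4 or 9 or spleen knockout 10. Itgb2l missed it without marrow knockout 5, spleen controls 3, 4 or 9 or spleen knockouts 6 or 10, Cd2 without marrow knockouts 5 or 6, spleen controls 3, 4 or 9 or spleen knockouts 8 or 10, and the regulatory T cell list without marrow control 1. The count was 18 without marrow control 1, 16 without marrow control 4, 15 without marrow knockout 10, 4 without marrow knockout 5, 4 without spleen control 3 or 4, 3 without spleen control 9 and 18 without spleen knockout 8.

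Marrow and spleen CD4 cells were also compared within each genotype, which describes the tissue background. Plasmacytoid dendritic cell genes were far higher in marrow: Siglech differed by 5.03 on the log2 scale between control marrow and control spleen (adjusted p = 0.00324) and by 5.29 in knockouts (adjusted p = 0.00161), and Cox6a2, Smim5 and Paqr5 by 3.71 to 5.65 in the 2 genotypes. Of genes on the T cell lists, Ly6c2 (2.88 and 2.65), listed for memory and effector cells, and Foxp3 (1.57 and 0.64) were higher in marrow in controls and knockouts. Il6ra (−1.18 and −1.54) and Igfbp4 (−2.08 and −3.60), markers of naive cells, were lower. The libraries also hold RNA of other cells, so the rise of Ly6c2 cannot be assigned to T cells. Macrophage genes were lower in marrow: Clu stood at −4.62 and −5.42 and the scavenger receptor gene Marco at −6.18 in knockouts. C6 and Adamdec1 were listed at 0 in all 3 control marrow libraries, which made them at least 77.5-fold and 76.2-fold lower than in control spleen by a floor of 3 counts over the group, and Apoc1 was at least 117-fold lower in knockout marrow by the same floor.

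In controls 406 of 12875 genes differed between the tissues (172 higher and 234 lower in marrow), and in knockouts 652 (212 and 440). For 397 and 629 of them the groups did not overlap, against 18.2% and 20.2% of all genes and 10% by chance. Other named genes higher in control marrow were Cd34, Cd209d, Cd300c, Elane, Wfdc21 and Eldr, and others lower were Clec4n, Treml4, Stab2, Timd4, Hfe, Cd300e and Adgre4. In knockouts Cd300c, Eldr, Cd209d, Klra17, Lifr and Ptprf were higher, and C6, Gng11, Clec4n, Csf1r, Clec1b, Treml4 and Nr1h3 lower. Of 40 lists, camera called 23 in controls, 7 of them also with an estimated correlation. In knockouts it called 15, 0 of them also with an estimated correlation. Memory and effector T cell genes had a median of 0.60 in controls (10 of 31 higher over all genes, 17 adjusted over the list alone, adjusted p = 0.0132 with an estimated correlation). In knockouts the median of this list was 0.26 (5 and 10 members higher, adjusted p = 0.15 with an estimated correlation). Plasmacytoid dendritic cell genes had a median of 2.49 in controls (9 of 15 members higher over all genes and 14 adjusted over the list alone, adjusted p = 0.0406 with an estimated correlation) and 2.52 in knockouts (13 and 14 members higher, adjusted p = 0.0516 with an estimated correlation). Neutrophil genes had a median of 3.04 in controls (10 higher and 1 lower, adjusted p = 0.0292 with an estimated correlation). Monocyte and macrophage genes had medians of −2.78 and −3.25 (adjusted p = 0.0365 and 0.0516 with an estimated correlation), and megakaryocyte genes −2.82 and −2.81 (adjusted p = 0.0340 and 0.0516 with an estimated correlation). Cell cycle genes (median 0.38) and stem cell genes (median 0.90) were the other 2 lists that held in controls, each with adjusted p = 0.0249 with an estimated correlation. The tissues come in separate tables, and the labels name no batch.

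In controls the count was 259 without marrow control 1, 255 without marrow control 9 and 241 without spleen control 9, and in knockouts it was 428 without marrow knockout 5 and 401 without marrow knockout 6. Siglech, Cox6a2, Smim5, Paqr5, Ly6c2, Foxp3, Il6ra, Igfbp4, Clu, Marco, C6 and Adamdec1 were called in controls, and Apoc1 in knockouts, whichever library was left out. In controls Cd209d, Cd300c, Clec4n, Hfe, Cd300e and Adgre4, and in knockouts Cd209d, Lifr, Clec1b and Nr1h3, each missed the threshold without 1 or more libraries, with adjusted p up to 0.144 for Adgre4 and up to 0.106 for Nr1h3.

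Single-cell sequencing of sorted marrow cells asked which cell classes and transcripts differed between a control and a knockout library. With 1 library per genotype there is no replicate check, and each interval covers counting error only. The sort for B220 and CD11c sets which classes appear and in which share. Plasmacytoid dendritic cell-like (pDC-like) cells, the main interferon producers, made up 58.6% of kept cells in the control (4422 of 7552; exact binomial 95% interval 57.4% to 59.7%) and 61.7% in the knockout (4240 of 6867; 60.6% to 62.9%). Cells like B cell precursors (pro-B and pre-B-like), which assemble antibody genes, had 2.21% in the control (1.89% to 2.57%) and 11.04% in the knockout (10.3% to 11.8%), a ratio of 4.99, or 2.71 with a loose cell filter. NK-like cells had 14.95% (14.2% to 15.8%) and 8.99% (8.32% to 9.69%), a ratio of 0.601, and B-like cells 10.1% and 9.89%, a ratio of 0.976. Plasma-like cells, which secrete antibody, numbered 414 in the control (5.48%; 4.98% to 6.02%) and 14 in the knockout (0.204%; 0.112% to 0.342%). Their median depth was 15061.5 and 1753 UMIs. The plasma-like ratio of 0.0372 became 0.606 with the loose filter, 0.156 when immunoglobulin and interferon genes were used in clustering and 0.0107, with 4 knockout cells left, without barcodes that had at least 8-fold more UMIs in the other library.

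**Figure D2:**
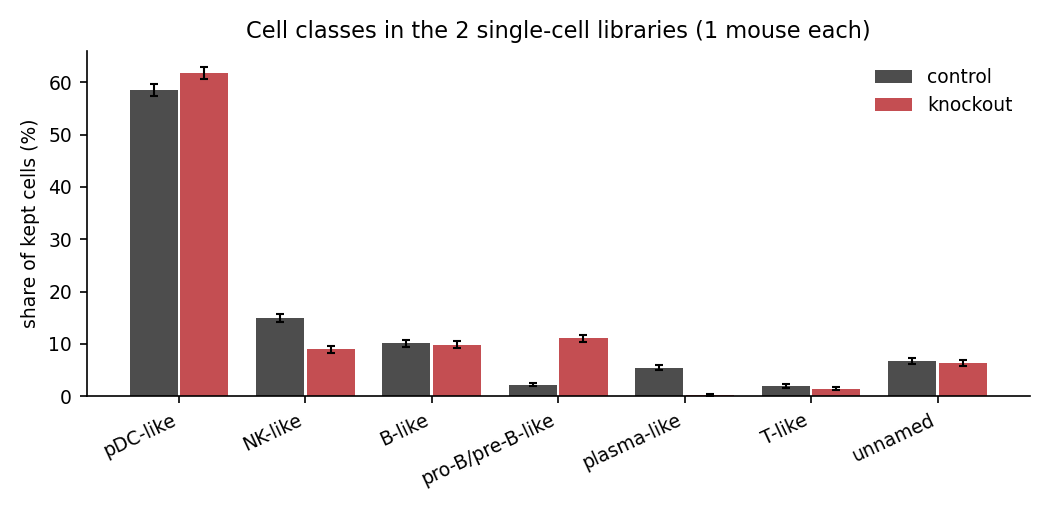
Share of kept cells (%) per cell class in the control library (7552 cells) and the knockout library (6867 cells), with exact binomial 95% intervals for counting error only. Pro-B and pre-B-like cells stood at 2.21% and 11.04% and plasma-like cells at 5.48% and 0.204%.

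Some of these classes were built from different clusters in the 2 libraries. Of the clusters of pro-B and pre-B-like cells, cluster 9 had 102 control and 337 knockout cells, cluster 12 had 58 and 267, cluster 23 had 6 and 88 and cluster 24 had 1 and 66. Clusters 25 and 27 of the B-like cells, whose leading genes both include the cell cycle gene Pclaf, had 42 and 31 control cells against 12 and 0 knockout cells, while clusters 3 and 8 had 501 and 191 control and 370 and 297 knockout cells. A cluster that comes mostly from 1 library may reflect that library and not a cell type. T-like cells had 145 and 101 cells. Both libraries held 873 barcodes in common, of which 774 had UMI totals at least 8-fold apart, 511 of them with the lower total in the knockout library.

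**Figure D3:**
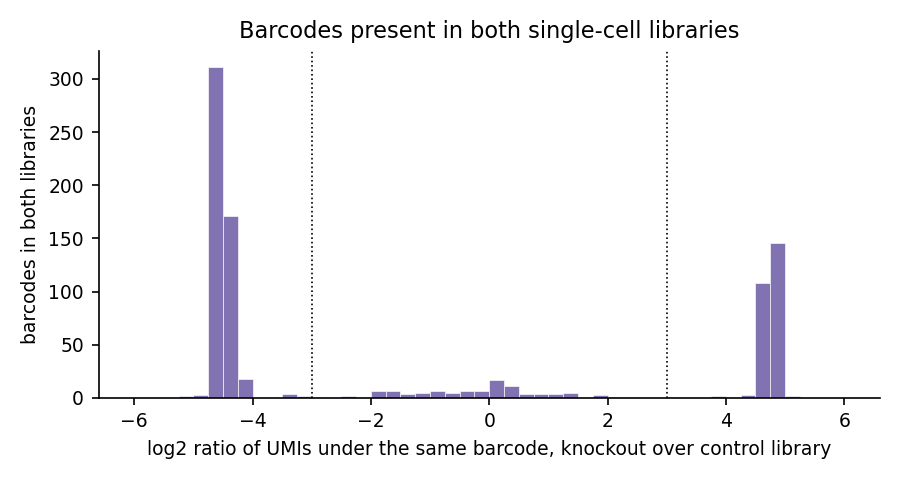
Number of barcodes found in both libraries (873) by the log2 ratio of their UMI totals, knockout over control, with dotted lines at an 8-fold difference either way. Totals lay at least 8-fold apart for 774 of them.

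Within pDC-like cells, genes of the type I interferon response were higher in the knockout library. Of 60 measured members 51 had a higher CPM, with a median log2 ratio of 0.20 (counting interval 0.132 to 0.238) at percentile 100 among 10000 random lists matched on size and mean expression, as a description of these libraries. Ifi27l2a had 652 CPM in the control and 794 CPM in the knockout (ratio 1.22, interval 1.19 to 1.25), Isg15, a ubiquitin-like modifier, 33.8 and 47.4 CPM (1.40, 1.27 to 1.55), and Ifi44 38.7 and 57.8 CPM (1.49, 1.36 to 1.64). Ifi44l had a ratio of 2.18 (1.97 to 2.42) and the antiviral synthetase Oas1a, with 12 and 66 UMIs, one of 5.31 (2.85 to 10.8). Bst2 stood at 0.960. A cluster led by interferon-induced genes held 60 of 4422 control (1.36%, exact binomial interval 1.04% to 1.74%) and 108 of 4240 knockout pDC-like cells (2.55%, 2.09% to 3.07%). Without that cluster the median log2 ratio of the list was 0.0383. Clustering left out the genes of the type I interferon list, though Iigp1 and Ifi207 lie outside it. Ifi27l2a (ENSMUSG00000079017) lies on chromosome 12 of mm10 from 103442167 to 103443680.

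Genes of cholesterol synthesis were lower in knockout pDC-like cells, 19 of 20 of them, with a median log2 ratio of −0.41 (−0.468 to −0.372) at percentile 0.0. Immediate early genes were higher (22 of 29, median 0.18, percentile 100), and so were genes of the interferon gamma response (22 of 32, median 0.07, percentile 99.5). Heat shock genes had a median of −0.15 with 4 of 13 higher. Genes of interferon induction, which include Tlr7, Tlr9 and Irf7, had a median of 0.00 with 14 of 27 higher (percentile 58.7), and the interferon genes themselves had 19 UMIs in 4422 control and 22 UMIs in 4240 knockout cells, nearly all of them Ifng. Among 4 measured Siglec genes 1 was higher, and Siglech, a receptor of plasmacytoid dendritic cells, had 2198 CPM in the control and 1994 CPM in the knockout (ratio 0.907, 0.895 to 0.920). MHC class II genes had a median of 0.00 and a mean of 0.08, with 6 of 12 higher.

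**Figure D4:**
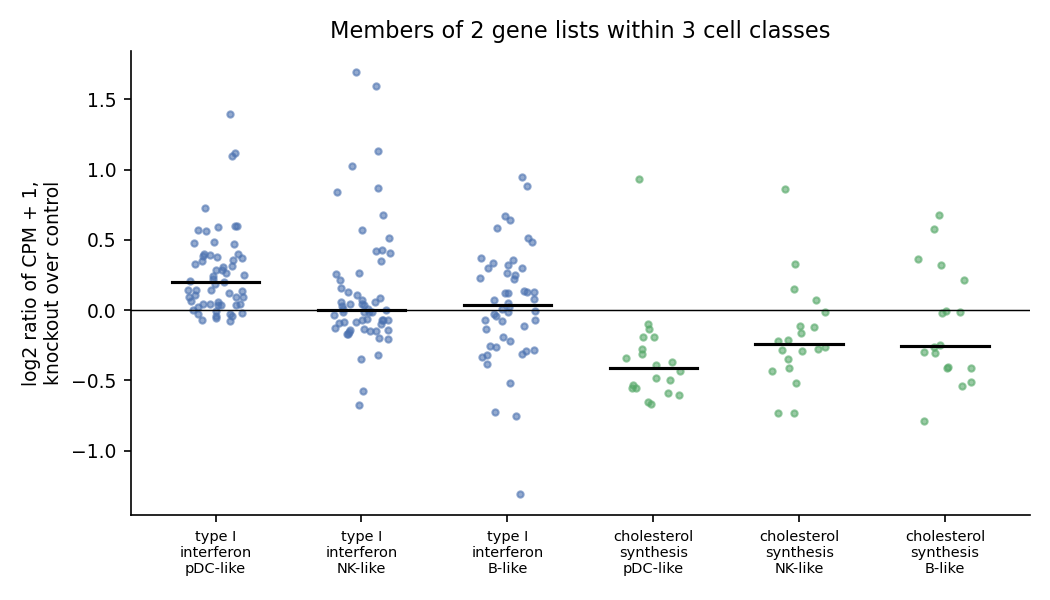
Log2 ratio of CPM plus 1, knockout over control, for each measured member (points) of the type I interferon response and cholesterol synthesis lists in pDC-like, NK-like and B-like cells, with the median as a black line. In pDC-like cells the medians were 0.20 and −0.41.

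By the rule for named genes, 65 genes of 9566 had at least a 2-fold higher and 31 at least a 2-fold lower CPM in knockout pDC-like cells. The largest ratios were those of D5Ertd615e (1 and 80 UMIs), Mpo (3 and 132), Ctsg (2 and 62) and Elane (7 and 89), the last 3 granule genes of early neutrophils, then Gstp1, Raver1, Camk4, Hist1h2ap, Hmga1 and Hspb2. The lowest were those of the immunoglobulin genes Ighg3 (1040 and 3 UMIs), Ighg2c (180 and 3), Jchain (1225 and 130), Igkc (26764 and 5004) and Iglc1, with Xlr3b, the neutrophil genes S100a9 (88 and 11 UMIs) and S100a8, Celf4 and the heat shock gene Hspa1a. Unnamed cluster 29, whose leading genes include Mpo, Ctsg and Elane, had 4 control and 20 knockout cells. Unnamed cluster 6, led by S100a8 and S100a9, had 349 and 161. Whether RNA of such cells was counted in pDC-like cells was not tested. Gstp1, a glutathione transferase, had 5.76 and 59.2 CPM in pDC-like cells (ratio 10.3, 8.47 to 12.6), with ratios of 9.79 in NK-like and 8.21 in B-like cells. It shares sequence with near-identical copies, as does Hist1h2ap.

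In NK-like cells the type I interferon list had a median log2 ratio of 0.00 with 30 of 59 members higher (percentile 55.2) and a mean of 0.13. Immediate early genes were higher (27 of 30, median 0.36, percentile 100), while cholesterol synthesis genes (4 of 20 higher, median −0.24, percentile 0.01), cell cycle genes (3 of 40 higher, median −0.16, percentile 0.0) and cytotoxic genes (4 of 14 higher, median −0.16, percentile 0.08) were lower. Genes of plasmacytoid dendritic cells were higher in these NK-like cells (14 of 15, median 0.71), for example Siglech with 41.2 and 92.3 CPM. Markers of conventional dendritic cells (9 of 10 higher, median 0.49), of B cells (10 of 15, 0.32) and MHC class II genes (8 of 10, 0.23) were higher there as well, and those of plasma cells (2 of 8 higher, median −2.11) and immunoglobulin constant genes (2 of 11, −2.47) were lower. Without doublet removal the medians of the cholesterol synthesis and type I interferon lists were 0.0265 and 0.206. The largest ratios were those of Hmga1 (10.4, 6.08 to 18.8), Gstp1, Lrch4, Hist1h2ap, Ctla2b (7.68, 4.64 to 13.4), Ccdc85b, Rpgrip1, Hs3st1, Sik1 and Igll1, and the lowest those of Ighg2c (51 and 0 UMIs), Ighg3, Jchain, Ighg2b, Rab4a, Igkc, Lyz2, S100a8, Iglc1 and Tpcn2.

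In B-like cells, 39 of 40 cell cycle genes were lower in the knockout, with a median log2 ratio of −1.83 at percentile 0.0, beside the lower cell numbers of clusters 25 and 27. Among the lowest ratios, Gcsam had 128 and 0 UMIs, Mef2b 186 and 4, Nuggc 62 and 0 and S1pr2 60 and 2. Immediate early genes were higher (22 of 27, median 0.33, percentile 100), and the type I interferon list had a median of 0.03 with 27 of 50 higher (percentile 75.8). The transcription factors Myb (ratio 3.91, 2.52 to 6.22) and Sox4 (2.89, 2.02 to 4.18) and the GTPase Gem (2.95, 2.08 to 4.23) were among the largest ratios, with Gstp1, Lrch4, Gas7, Sik1, Rab3a, Psme2b and Slamf9. The lowest ratios also included Jchain (392 and 3 UMIs), Cenpe, Ighg3 and Plk1.

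In pro-B and pre-B-like cells the type I interferon list had a median log2 ratio of 0.26 with 35 of 47 members higher (percentile 100), and cytotoxic genes one of 0.57 with 9 of 11 higher. Markers of NK and NKT cells (10 of 13 higher, median 0.57) and thymocytes (4 of 6, 0.75) were higher beside them, and those of plasmacytoid dendritic cells were lower (2 of 15 higher, median −0.56). Gzmb, a granule protease, had 0 UMIs in the control and 74 in the knockout, and Olfr889 had 0 and 56. Ighg3 had 54 and 1 UMIs and Jchain 55 and 11. These ratios compare 167 control with 758 knockout cells that lie in different shares of the 4 clusters. In T-like cells immediate early genes were higher (18 of 22, median 0.47, percentile 100), MHC class II genes were lower (2 of 9 higher, median −1.03, percentile 0.0) together with markers of B cells (0 of 8 higher, median −0.95), of conventional dendritic cells (0 of 4, −0.93) and immunoglobulin constant genes (0 of 7, −2.09), and the type I interferon list had a median of 0.15 (22 of 35 higher, percentile 99.5) with a counting interval of −0.062 to 0.318, which spans 0. Markers of NK and NKT cells (12 of 15 higher, median 0.15, percentile 99.7) and mitochondrially encoded genes (11 of 12 higher, median 0.19, percentile 100) were higher by as much. Sytl3 had the largest ratio there, at 6.27, and Ccl4, a chemokine, had one of 0.307.

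Immunoglobulin transcripts were also counted per pDC-like cell, since this lineage can transcribe heavy chain genes. After thinning each cell to 1500 UMIs, Igkc was present in 82.4% of control (3605 of 4377; exact binomial interval 81.2% to 83.5%) and 14.3% of knockout pDC-like cells (603 of 4206; 13.3% to 15.4%). In NK-like cells, which do not express it, the shares were 76.6% and 9.18%, and in T-like cells 75.7% and 7.92%, so most of the Igkc share lay at the background of each library. Ighm was present in 95.2% of control (94.6% to 95.8%) and 91.4% of knockout pDC-like cells (90.6% to 92.3%), against 53.4% and 39.7% in NK-like and 62.9% and 41.6% in T-like cells. Median depths before thinning were 4187 and 4506 UMIs in pDC-like and 5389 and 5655 UMIs in NK-like cells, and without thinning the Igkc shares in pDC-like cells were 98.7% and 30.2%.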

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

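Tests chosen only after the result was seen were the counts of other splits of the libraries and the fits with the Xist level as a covariate. The comparison of lower and higher marrow genes with single T-like and B-like cells was also chosen then. The share of the free RNA test with 3 immunoglobulin genes added was also computed after its result on the set was seen. The other tests in this part had their predictions written before the result they measure, although the patterns themselves, the agreement of cell classes under shared barcodes and the names of the genes that moved alike had been seen.

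Genotype effects that differed between marrow and spleen by the edgeR interaction test stood out for 7 genes. The interaction was −1.06 for Cd247, −0.93 for Foxp3 (−0.929), −0.75 for Cd5 (−0.748), −0.72 for S100a10 (−0.716) and −0.67 for Cd2 (−0.665). For the neutrophil genes it was −4.05 for Elane and −7.68 for Itgb2l, the latter a fitted value against control spleen libraries listed at 0. Of 100 splits drawn from 200 possible ones, 5 gave as many as 7 genes, the real one included, and the highest other gave 28, so chance is not excluded. Of the 4 other splits, those with 28, 15 and 14 genes keep control and knockout marrow libraries apart and mix the spleen libraries, so they still hold the marrow genotype difference and are no reference without it. The remaining one, with 12 genes, mixes control and knockout libraries in both tissues. In spleen it parts controls 4 and 9 and knockout 8 from control 3 and knockouts 6 and 10, which follows the Xist level. In marrow, control 1 and knockouts 5 and 10 had Xist at 604, 490 and 396 CPM. Controls 4 and 9 and knockout 6, on the other side, had 157, 147 and 517 CPM. So none of the 4 is a reference free of other structure, and the count of splits cannot decide on chance.

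In marrow the real split called 85 genes and the highest other 7, with 1 of 10 splits as large, the real one included. In spleen the real split called 4 and the highest other 29, with 4 of 10 as large, which points to another structure of the spleen samples. The split with 29 genes parts control 3 and knockouts 6 and 10 (Xist at 386.5, 402 and 338 CPM) from controls 4 and 9 and knockout 8 (166, 131 and 146 CPM), so it follows the Xist level. With that level as a covariate the genotype comparison in spleen called 4 genes, 3 higher and 1 lower, of which 3 were shared with the fit without it. Between tissues the real splits called 406 genes in controls and 652 in knockouts, and the highest other called 0 in each, with 1 of 10 as large. With 10 splits of 6 libraries these are too few for a share under 0.05.

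The first pattern is the lower level of T cell genes in knockout marrow, where the median log2 fold change of 9 T cell markers was −0.57. Gene counts of the marrow groups did not overlap, at 6418293 to 6810485 in controls and 8653386 to 8791627 in knockouts. Genes detected ran the other way, at 13630 to 13753 and 13247 to 13413. A difference in depth alone is argued against, since with every library thinned to 6418293 counts the median was −0.56 (−0.559) and 93 genes were called. Thinning evens depth only, so any other difference in how the groups were prepared or sequenced cannot be told apart from genotype. Fewer T cells beside B cells in the knockout libraries, although a sort for CD4 would remove B cells, is a candidate explanation. Of 52 lower genes measured in single cells, 94.2% were higher in T-like than in B-like cells, against 46.4% of all tested genes. A genotype effect within T cells would lower such genes too, so this share cannot tell these explanations apart. Of 24 higher genes measured in single cells, 12.5% were higher in T-like and 21 genes were higher in B-like cells. All 14 tested B cell markers rose, with a median of 0.27. A fall within T cells alone would leave that rise unexplained, though it could occur beside fewer T cells. The T-like cells were 1 cluster of 246 cells led by Trdc and Ccl5, not sorted CD4 cells. The basophil and megakaryocyte lists (medians −0.92 and −0.57, camera adjusted p = 0.00816 and 0.0146, and adjusted p = 0.336 and 0.296 with an estimated correlation) lay opposite to the B cell list. The basophil list was not called without control 4 or knockout 6, nor the megakaryocyte list without control 4. Of the 58 lower genes, 8 lay below the marker median by more than 2 SE: Mnda, Eid2, Igfbp4, Ccdc92, Dnaja4, Pdcd1, Cd247 and Gimap7. With the Xist level as a covariate the median was −0.48 (−0.476, interval −0.564 to −0.335, against −0.593 to −0.481 without it). These intervals resample the 9 marker genes and not the libraries, and genes are not independent replicates. The median standard error rose from 0.0931 to 0.109, and 4 of the 9 markers were past the threshold instead of 7. Lat (−0.34, adjusted p = 0.261), Bcl11b (−0.47, adjusted p = 0.298) and Thy1 (−0.49, adjusted p = 0.351) missed it. So a difference in the share of female RNA cannot be told apart from genotype, and a genotype effect within T cells stays open.

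The second pattern is the set of 774 barcodes found in both single-cell libraries with UMI totals at least 8-fold apart, where the weaker total had a median of 4.15% of the stronger. Reuse of barcodes by chance is argued against by plasma-like pairs, of which 239 shared their leading heavy chain constant gene, while the highest of 1000 shufflings gave 174. Reads of 1 library counted in the other may be a candidate explanation, since the gene was shared in 100% of those pairs with enough UMIs. Both members had the same class in 97.0% of 575 named pairs. No biological explanation was tested.

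The third pattern is a set of 11 genes, of 4943 measured outside the immunoglobulin genes, that, like the immunoglobulin genes Jchain, Igha and Ighg3, differed at least 2-fold the same way in pDC-like, NK-like and B-like cells, among them Gstp1, Hist1h2ap, Eno1, Lrch4, Rpl35 and Vpreb3. Reads shared with near-identical copies may be a candidate explanation: 81.8% of the 11 (9 genes) had a copy sharing 60 bases near the transcript end, against 31.4% of 220 matched genes (Fisher's exact test, two-sided, p = 0.00118). Free RNA of a cell class is argued against for the set, since 9.09% of the 11 (Vpreb3 alone) were at least 10-fold higher in one class than in the median class, while Rpl35 had 4250 CPM in its highest class against a median of 2270 and Gstp1 101 against 33.0. It stays open for Vpreb3 and for the 3 immunoglobulin genes outside the set, which were highest in plasma-like cells (Jchain 14400 CPM against 27.1) and with which the share is 28.6% of 14. A genotype effect in all cells cannot be told apart, because the marrow bulk libraries measured 3 of the 11 genes, and in other cells. Their median change, signed by the single-cell direction, was −0.24 (−0.236, range over the 3 genes −0.517 to −0.0693), so it ran against that direction. The copies do not say why the libraries differ in them.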

How the results depend on the processing

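The Xist covariate, the doublet score above 0.25, the data without barcodes of the other library and without the interferon-led cluster were chosen only after the result was seen; the others were planned. The cause of each shift below was not tested, except that a minimum fold change lowers counts by construction. Leaving out genes of other cell types also removes Elane, Camp and Lcn2 from the spleen test by construction. Of the log2 fold changes of named genes under all alternatives, 5864 kept direction and were not seen to change side of the threshold. Any value that DESeq2 left without an adjusted p is counted among them, though its side is unknown. Another 841 lost the call, 203 gained it and 6 reversed, all 6 of them for St3gal1 or Pf4.

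Genes called in marrow numbered 243 without an expression filter, 202 with DESeq2, 7 with a log2 fold change of at least 1 as well, 56 in the 4-group fit and 15 with the Xist covariate, and 11 (without control 9) to 133 (without control 1) when 1 library was left out. In marrow DESeq2 gave no adjusted p for 8875 of 12044 genes and so adjusted over fewer. In spleen they numbered 36, 19 and 1 without a filter, with DESeq2 and in the 4-group fit, 0 without genes of other cell types (edgeR, 560 at an unadjusted p under 0.05), and 2 to 42 without 1 library (42 without knockout 8). The interaction had 61 without a filter, 26 with DESeq2, 2 with limma-voom, 3 with a log2 fold change of at least 1, and 3 to 18 without 1 library. With library numbers as a replicate block it had 44 as a fixed term and 2 as a random effect. The 44 were 16 higher and 28 lower, and 4 of the 7 genes called without a block were among them. Correlations of deviations between libraries with the same number ran from −0.00038 to 0.0499, all under the 0.1 set for pairs, so the numbers were not taken as pairs. As a hint from the data, 3 of the 4 marrow libraries with a same-numbered spleen library correlated best with it (controls 9 at 0.0499, knockouts 6 at 0.0138 and knockouts 10 at 0.0236), while marrow control 4 correlated best with spleen control 9 (0.0260). The Xist levels of same-numbered libraries lay near each other (157 and 166 CPM for controls 4, 147 and 131 for controls 9, 517 and 402 for knockouts 6, 396 and 338 for knockouts 10), so whether a number marks a mouse stays open. Between tissues, controls had 616 without a filter, 218 with a log2 fold change of at least 1 and 241 to 460 without 1 library, and knockouts 307 with a log2 fold change of at least 1 and 401 to 687 without 1 library. With the Xist covariate St3gal1 in marrow stood at 0.02 (0.0249), Pf4 at 0.76 in marrow and 0.06 (0.0559) in spleen, and Pf4 in spleen ran from −0.80 (without knockout 10) to 0.73 (without control 9).

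Lists were counted under an estimated correlation or fry only where camera at its preset correlation called them too. With an estimated correlation 0 of the camera lists held in marrow, 0 in spleen and 0 for the interaction. Between tissues 7 held in controls and 0 in knockouts. Of the camera lists, fry called 1 in marrow, 0 in spleen and 1 for the interaction. Lists called by an alternative alone are not counted here. Marrow lists numbered 10 (without knockout 5) to 18 without 1 library.

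Shares of cells, knockout over control, moved with the loose filter to 0.872 for B-like, 0.695 for NK-like, 1.00 for pDC-like, 0.606 for plasma-like and 2.71 for pro-B and pre-B-like cells. In the loose set 261 of 265 knockout plasma-like barcodes had at least 8-fold more UMIs in the control library. Without doublet removal NK-like cells had 0.6965 and pDC-like 1.002, with immunoglobulin and interferon genes in clustering B-like had 0.865 and plasma-like 0.156, with the doublet score B-like had 0.877, and without barcodes of the other library plasma-like had 0.0107.

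The type I interferon list had a median of −0.13 (−0.128) in B-like cells at resolution 0.5, 0.21 (0.206) in NK-like cells without doublet removal and 0.04 (0.0383) in pDC-like cells without the interferon-led cluster. In B-like cells the interferon gamma list reversed to −0.0101 (resolution 0.5) and −0.00173 (loose filter), the B cell list to −0.0135 (cells weighted equally), −0.04 (resolution 0.5) and −0.0181 (loose filter), glycolysis to 0.0314 (resolution 0.5) and 0.029 (loose filter), and ribosomal proteins to 0.00498 (with immunoglobulin genes) and 0.00431 (doublet score). In NK-like cells the NK list reversed to 0.00397 (other totals), cholesterol synthesis to 0.0265 and the unfolded protein response to 0.0235 (no doublet removal). Ly6a in T-like cells reversed to 0.60 (no doublet removal) and 0.50 (doublet score).

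Igkc shares of pDC-like cells in the control were 98.7% unthinned, 84.5% at 3 UMIs or more, 81.1% with the loose filter and 81.17% with the doublet score, and in the knockout 30.2% and 7.19% for the first 2. Ighm shares were 99.7% and 97.6% in the control and 99.69% and 94.8% in the knockout.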

Other observations

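No test in this part was chosen after the result was seen. Enzymes of O-glycan and sialic acid synthesis, the class to which St3gal1 belongs, did not move together in CD4 cells. In marrow 0 of 33 passed edgeR over all genes (14 were positive), with a median log2 fold change of −0.01, a mean of 0.01 and a camera test directed up (adjusted p = 0.714), and in spleen the median over 34 was 0.03 (adjusted p = 0.842). In pDC-like cells 16 of 29 had a higher CPM in the knockout, with a median log2 ratio of 0.02 at percentile 45.4 among matched lists, as a description of these libraries. Siglec genes, whose products bind sialic acid, had a median of 0.18 over 6 genes in marrow (adjusted p = 0.186), where Cd22 rose, and 0.24 in spleen (adjusted p = 0.156).

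The list of inhibitory receptors of T cells, which also holds the ectonucleotidase Entpd1, had 2 members that fell in marrow, Pdcd1 and Entpd1, among 13 tested. It was not called (camera adjusted p = 0.484). Follicular helper T cell genes had 1 that fell among 15, again Pdcd1 (adjusted p = 0.148).

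Ddx3y, a Y-linked gene, had a UMI in 0 of 7552 control and 0 of 6867 knockout cells, while Xist had one in 95.4% and 88.2% of cells. Clusters left unnamed held 6.69% of control and 6.35% of knockout cells.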
